A study of Mus musculus with 32 samples.

How the data were processed

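RNA was measured in gastrocnemius muscle of 32 mice aged 10 weeks on a mixed background. The 8 groups were made of 2 genotypes at 4 Zeitgeber times (0, 6, 12 and 18 h), with 4 mice in each. Per the labels, mutant mice carried Sf1-Cre with both Sirt1 alleles floxed. The labels call the other mice controls only, and the series description gives them floxed alleles and no Cre, so that the Cre transgene and the deletion cannot be separated by this design. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns and treated with DNase. Stranded mRNA libraries were then sequenced from 1 end over 100 cycles in 4 pools of 8 samples. Which sample went into which pool was not given in the sources used here, so no correction for pools was made. Per the labels, the samples of ZT0 and ZT12 carried the same set of index sequences, and those of ZT6 and ZT18 another set. This layout allows a separate pool for each time but does not show it. In that case an effect of the pool would enter the rhythm tests and could not be separated from time.

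The values are FPKM, fragment numbers scaled by the length of the transcript and by the mapped total of the library, 1 value per gene and library, computed by the authors. Per the submitters' processing notes, the genome build was mm10. The aligner, the quantifier, the gene annotation and any scaling between libraries beyond FPKM were not given in the sources used here. The columns name the genotype, the time and a library number from 0 to 3, and they were matched to the 8 groups by the genotype and the time. The library number does not identify the mouse, and libraries with the same number were not treated as pairs. A further table with the authors' own rhythm statistics was not used here.

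FPKM values carry no read counts, so absolute depth is unknown and no model for counts was used. In 921 genes above 0 in 6 to 20 libraries, low values fell in steps. Of these values, 72.5% lay within 0.1 of a whole multiple of the smallest step, against 20% with no steps, and the steps gave relative depths from 0.815 to 1.31. Some abundant genes are listed at exactly 0 in part of the libraries. Acta1, the actin of skeletal muscle, is listed at 0 in 12 libraries (6 of each genotype) and lies between 17234 and 23914 FPKM in the others. Atp2a1, the calcium pump of fast fibres, is listed at 0 in 17 libraries (9 control and 8 mutant). The libraries that list Acta1 at 0 had a mean relative depth of 1.12, against 0.943 in the others, and an exact 0 in these values is therefore not taken as absence of RNA. For genes with exact zeros, values are given by library or as a range. The table also holds 256 entries with more than 1 gene symbol. In 23 entries the symbol has the form of a date, as a spreadsheet program writes it. Reference names for mm10 held 94.7% of the symbols. The highest Xist value was 0.0829 FPKM and the lowest Ddx3y value 26.8 FPKM, so all libraries had the pattern of male mice and sex was not used as a covariate. Nr5a1, which encodes SF1, the fast myosin gene Myh4 and genes of the mitochondrial genome were not analysed here.

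Differences were computed on log2(FPKM + 1), on which the change of genes with low values is understated. Of 16634 genes, the 11975 with at least 1 FPKM in at least 4 of the 32 libraries were tested. A linear model with 1 mean per group was fitted to all libraries with limma 3.58.1 (trended prior, 24 residual and 3.37 prior degrees of freedom) in R 4.3.3, and 2-sided p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The contrasts were mutant minus control over all times and at each time, and an F test of the dependence of the genotype difference on time. Rhythms were tested with an F test of the 24 h cosine and sine contrasts in each genotype and of their difference between genotypes; amplitude is given as log2 from mean to peak. With 4 times, the third contrast between times is a 12 h component, which the 24 h test leaves out. The limma p-values set differences against the spread between mice of a group. The day of each harvest was not given in the sources used here, and an effect of a shared day would enter the rhythm tests.

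In total 30 gene lists for the clock, muscle metabolism, fibre type, stress responses and cell types were written, of which 28 had at least 5 tested genes. Lists were tested with camera (preset correlation 0.01) over 28 lists and 5 genotype contrasts, 140 tests in all, and again with a correlation estimated for each list and with fry. Enrichment of lists for rhythmic genes was tested with a 1-sided Fisher's exact test against all 11975 genes tested. That test takes genes as independent and does not use the spread between mice. The amplitude ratio and the phase shift of core clock genes and the Sirt1 level were tested with permutations of genotype within each time (100000 draws, 2-sided). These tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated.

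For each limma test, the rule names the 10 genes with the largest rise and the 10 with the largest fall among those that passed with a mean of at least 1 FPKM, and for rhythms the 20 with the largest amplitude. Tests of interaction and rhythm difference take the 20 with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p are added as not passing. Symbols of predicted genes are counted and not named, core clock genes and Sirt1 may be named throughout, and each list adds up to 4 members with the smallest p. Not all of these genes are printed.

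The model was tested on simulated data, in which 200 of the 11975 genes were changed on the log2(FPKM + 1) scale. The noise was made of the residuals of the real genes, shuffled within each gene. Correlation between genes and structure shared by libraries were thereby lost, so the shares below need not hold for the real libraries. For genotype over all times, 91% of changes of 0.5 and 97% of changes of 1 (log2) were recovered. At single times the share was 47.5% to 58% for 0.5 and 91% to 96.5% for 1. For the dependence on time, simulated as a change of 0.5 or 1 at ZT0 only, it was 27.5% and 81.5%. For the rhythm difference, simulated as a 24 h cosine with an amplitude of 0.5 or 1 in mutants only, it was 76.5% and 96%. These patterns are unlike, so the shares of the 2 tests cannot be compared. Alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalisation, array weights, fits of only the groups compared, other forms of the rhythm test and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3. Gene positions are those in the authors' table. Gene types, strands and the distance between Nr5a1 and Nr6a1 were taken from a GENCODE annotation of the same build.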

Results

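The series asks whether SIRT1, an NAD-dependent deacetylase, acts in SF1 neurons on the daily variation of RNA in skeletal muscle. SF1 neurons lie in the ventromedial hypothalamus, a brain region that regulates energy balance. Gastrocnemius, a hind limb muscle made mainly of fast fibres, was compared between mice with Sf1-Cre and floxed Sirt1 (mutants) and controls without Cre. The cross directs the deletion of SIRT1 to SF1 neurons, and where the deletion took place was not measured here. Muscle was taken at Zeitgeber times (ZT, in hours from lights on) 0, 6, 12 and 18. With 4 mice per genotype and time, 32 libraries entered 8 groups, and RNA abundance was given as FPKM. Relative depth, read from steps in the low values, was 0.990 ± 0.146 in controls and 1.03 ± 0.144 in mutants (SD, n = 16 each), and absolute depth is unknown.

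Sirt1 RNA was present in the muscle of every mouse, and its level did not differ detectably between genotypes. Sirt1 (XLOC_002098, chromosome 10, 63319005 to 63339035 in mm10) was at 5.47 ± 0.506 FPKM in controls and 5.20 ± 0.731 FPKM in mutants (SD, n = 16 each). Control libraries ranged from 4.57 to 6.65 FPKM and mutant libraries from 4.02 to 6.32 FPKM. The difference on the log2(FPKM + 1) scale was -0.07 (permutation of genotype within time, p = 0.167). The deletion was directed at SF1 neurons, which were not measured here, so this value describes the muscle and does not check the deletion.

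Between genotypes over all times, 3 genes differed, all of them higher in mutants and all on chromosome 2. Nr6a1, which encodes an orphan nuclear receptor, rose from 1.17 ± 0.238 FPKM in controls to 2.58 ± 0.357 FPKM in mutants (SD, n = 16 each). The lowest mutant library (2.02 FPKM) lay above the highest control library (1.65 FPKM). Gm13490, a long intergenic RNA, was between 0 and 0.111 FPKM in control libraries and between 0.238 and 2.65 FPKM in mutant libraries. Arl5a, a small GTPase of the Golgi, rose from 8.89 ± 0.907 to 11.6 ± 1.48 FPKM.

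The log2 difference was 0.72 for Nr6a1 (SE 0.0479, limma adjusted p = 1.03e-10), 1.34 for Gm13490 (SE 0.104, adjusted p = 2.43e-09) and 0.35 for Arl5a (SE 0.0551, adjusted p = 0.00320). Nr6a1 (XLOC_012290) lies at 38723374 to 38926461 on chromosome 2, Gm13490 (XLOC_012305) at 51656966 to 51732009 and Arl5a (XLOC_012309) at 52397951 to 52424874, all on the minus strand. Gm13490 falls outside the rule for naming genes and was chosen after its values were seen. It is listed at 0 in some control libraries, so no fold is given. The next genes by p did not pass. Lypd6, also on chromosome 2, was at 2.62 ± 0.479 FPKM in controls and 1.86 ± 0.535 FPKM in mutants (adjusted p = 0.121). Tnik, a kinase, was at 7.69 ± 1.01 and 6.52 ± 1.12 FPKM (adjusted p = 0.144, and 0.0415 with array weights), and the histone demethylase gene Kdm1a at 13 ± 0.813 and 11.7 ± 0.830 FPKM (adjusted p = 0.220). In all, 776 of 11975 genes had an unadjusted p under 0.05, 397 higher and 379 lower in mutants. With a minimum mean of 5 FPKM only Arl5a was among the genes tested and 1 gene passed. Lypd6 passed without control ZT0 library 1 (adjusted p = 0.0220) or without mutant ZT18 library 1 (adjusted p = 0.00329), and its difference was then -0.38 and -0.39.

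**Figure D1:**
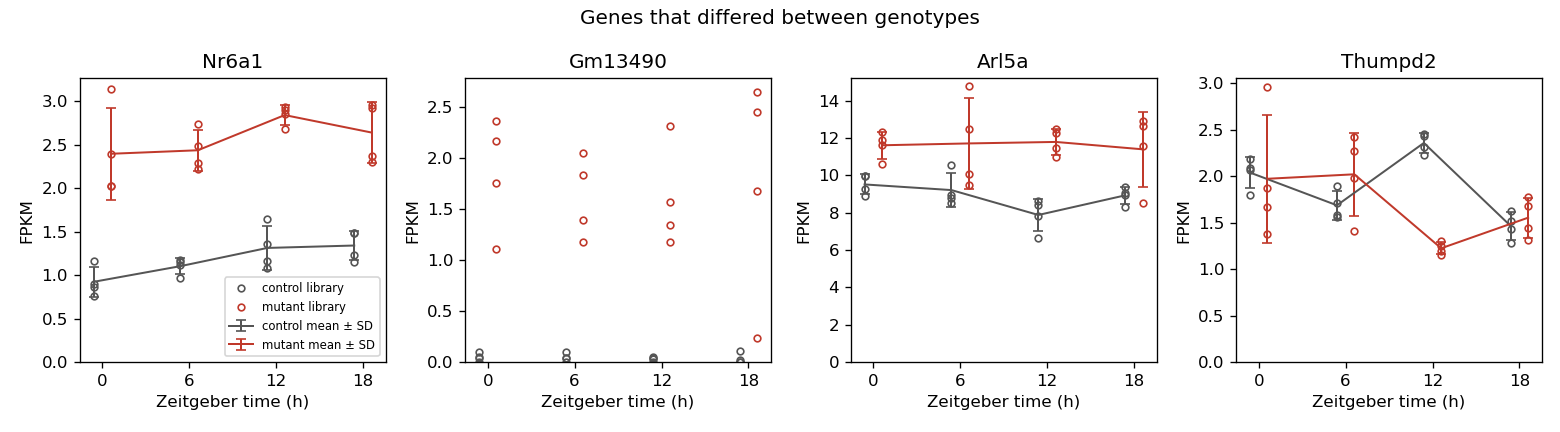
FPKM of Nr6a1, Gm13490, Arl5a and Thumpd2 (vertical axes) against Zeitgeber time in hours (horizontal axes), with 1 open circle per library in controls (grey) and mutants (red), slightly offset; lines join group means and bars show the SD of 4 mice, except for Gm13490, which is drawn without means because control libraries are listed at 0. Mutant libraries of Nr6a1 lie between 2.02 and 3.14 FPKM at all times, and 1 mutant library at ZT18 has 0.238 FPKM of Gm13490 and 8.52 FPKM of Arl5a.

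Over all times, genes of lymphocytes and fat cells and genes of lipid synthesis had higher means in mutants, and genes of slow fibres and of the glucocorticoid response lower means. None of these list calls held with an estimated correlation (adjusted p = 0.933 with an estimated correlation for each). All 22 lymphocyte genes had higher means in mutants, with a median log2 difference of 0.53 (camera adjusted p = 3.31e-09 with the preset correlation, adjusted p = 0.933 with an estimated correlation). The same loss holds for the adipocyte and lipid lists. Among them the T cell receptor gene Cd3e was at 1.62 ± 1.02 FPKM in controls and 2.82 ± 2.04 FPKM in mutants, and the leukocyte phosphatase gene Ptprc at 4.02 ± 4.83 and 6.54 ± 4.87 FPKM (n = 16 each; adjusted p = 0.756 for both). Of 20 adipocyte genes, 18 were higher (median 0.43, adjusted p = 0.000316), such as the leptin gene Lep (3.11 ± 2.14 and 5.20 ± 3.35 FPKM, adjusted p = 0.756). Of 29 genes of lipid synthesis and storage, 27 were higher (median 0.17, adjusted p = 5.32e-07), and 3 of these genes also stand in the adipocyte list. Scd1, the stearoyl-CoA desaturase gene in both lists, was at 198 ± 191 FPKM in controls and 482 ± 442 FPKM in mutants.

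All 19 slow fibre genes had lower means in mutants, with a median log2 difference of -0.22 (camera adjusted p = 9.43e-07 with the preset correlation). For this list and every other list of this paragraph, adjusted p = 0.933 with an estimated correlation. Tpm3, the slow tropomyosin gene, was at 218 ± 71.2 FPKM in controls and 159 ± 54.2 FPKM in mutants, and Myl2, a slow myosin light chain gene, at 502 ± 134 and 398 ± 121 FPKM (adjusted p = 0.756 for both). Of 26 genes of the glucocorticoid response, 25 were lower (median -0.15, adjusted p = 5.32e-07). Zbtb16, a glucocorticoid-induced transcription factor, was at 12.9 ± 3.11 FPKM in controls and 9.65 ± 1.70 FPKM in mutants (adjusted p = 0.555). Smaller camera calls over all times were the fast fibre genes (18 of 19 lower, median -0.08), the atrophy genes (15 of 20 lower, median -0.08), heat shock genes (24 of 36 lower, median -0.03), smooth muscle genes (11 of 13 lower, median -0.07), macrophage and neutrophil genes (15 of 17 higher, median 0.18) and interferon genes (20 of 25 higher, median 0.05).

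No single gene of these lists passed limma over all genes. The counts at an unadjusted p under 0.05 were 2 lymphocyte, 1 adipocyte, 3 lipid, 7 slow fibre and 5 glucocorticoid genes. Adjusted over the list alone, 1 glucocorticoid gene passed and 0 genes of the other 4 lists did. Over 28 lists and 5 contrasts, 40 of 140 camera tests passed, and none of them did with an estimated correlation (smallest adjusted p = 0.933 with an estimated correlation) or with fry (smallest adjusted p = 0.544). Permuting genotype within time, the difference of the mean score of a list was -0.20 for slow fibre genes (permutation p = 0.0246), -0.19 for glucocorticoid genes (p = 0.0322), 0.30 for lipid genes (p = 0.0515), 0.53 for lymphocyte genes (p = 0.104) and 0.46 for adipocyte genes (p = 0.161). None of these 5 lists, chosen after the camera result was seen, passed after adjustment (adjusted p = 0.0806 for the first pair, 0.0858, 0.130 and 0.161). The lymphocyte and adipocyte scores varied widely within groups, from -1.09 to 1.52 and from -1.56 to 1.56 on the log2 scale, and with both as covariates 22 of 140 camera tests passed.

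**Figure D2:**
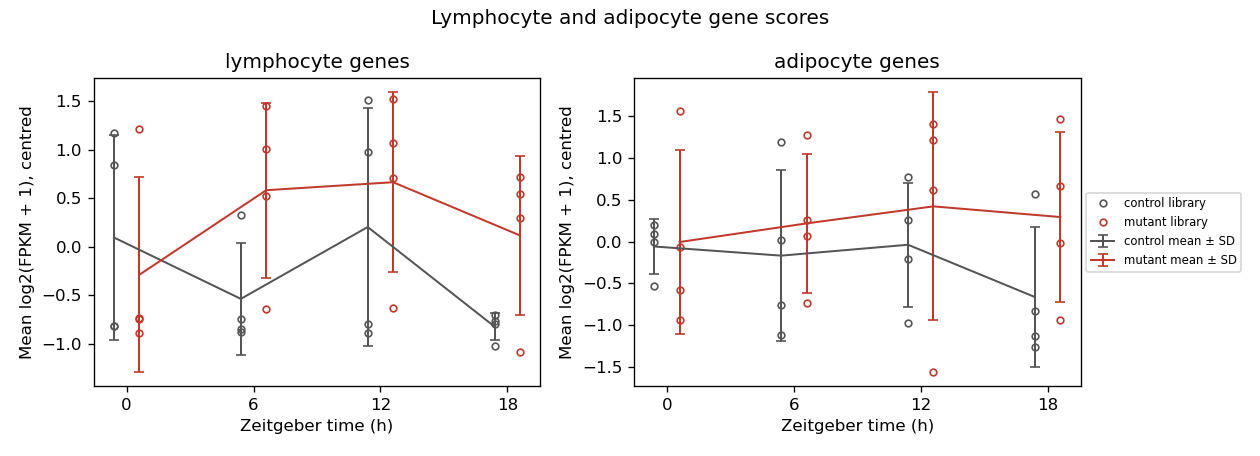
Mean centred log2(FPKM + 1) of 22 lymphocyte genes and 20 adipocyte genes (vertical axes) against Zeitgeber time in hours (horizontal axes), with 1 open circle per library in controls (grey) and mutants (red), slightly offset; lines join group means and bars show the SD of 4 mice. Libraries of 1 group spread over most of the range, as in control ZT12, where the lymphocyte score runs from -0.89 to 1.51.

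At each time, Nr6a1 and Gm13490 were higher in mutants, and at ZT12 Thumpd2, which encodes an RNA methyltransferase-like protein, was lower. The Nr6a1 difference was 0.81 at ZT0, 0.71 at ZT6, 0.74 at ZT12 and 0.63 at ZT18 (SE 0.0958 each; limma adjusted p = 4.63e-05, 0.000682, 0.000306 and 0.00461). Gm13490 passed at the same times, with adjusted p = 0.00131, 0.00561, 0.00481 and 0.00637. With only the groups compared in the fit, Gm13490 did not pass at ZT12 (adjusted p = 0.0635) or ZT18 (0.868), with quantile normalisation at ZT6 (0.459), ZT12 (0.0542) or ZT18 (0.520), and with array weights at ZT0 (0.178), ZT12 (0.0582) or ZT18 (0.0554). It was also lost at ZT6 without mutant ZT6 library 1 (0.0589) and at ZT18 without mutant ZT18 library 0 (0.0807) or 2 (0.0814). With only the groups compared in the fit, Nr6a1 did not pass at ZT0 (adjusted p = 0.558), ZT12 (0.151) or ZT18 (0.324), and with quantile normalisation it did not pass at ZT6 (0.106) or ZT18 (0.151). Thumpd2 (XLOC_009652, chromosome 17, 81026327 to 81065085) fell from 2.36 ± 0.107 FPKM in controls to 1.23 ± 0.0667 FPKM in mutants at ZT12 (n = 4 each; -0.59, SE 0.111, adjusted p = 0.0459). At ZT6 its means were 1.69 ± 0.155 and 2.02 ± 0.446 FPKM.

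Among genes that did not pass at ZT0, the muscle methyltransferase gene Mettl21c was at 78.0 ± 30.4 FPKM in controls and 155 ± 36.4 FPKM in mutants (adjusted p = 0.348). At ZT6, Sgk1, a kinase induced by glucocorticoids and insulin, was at 78.2 ± 11.2 and 43.2 ± 14.3 FPKM, Apobec2, a muscle gene of the deaminase family, at 490 ± 48.8 and 348 ± 39.9 FPKM, and Egr1, an immediate early gene, at 1.54 ± 0.435 and 5.06 ± 3.04 FPKM (adjusted p = 0.471 for each). With array weights Sgk1 (adjusted p = 0.0362), Apobec2 (0.0362) and Egr1 (0.0252) passed. At ZT12, Arl5a was at 7.88 ± 0.878 and 11.8 ± 0.691 FPKM and Rab6a, a GTPase of Golgi traffic, at 26.6 ± 0.241 and 38 ± 2.09 FPKM (adjusted p = 0.0549 for both). Both passed without mutant ZT0 library 2 (adjusted p = 0.0236 and 0.0142), mutant ZT0 library 3 (0.0262 and 0.00792) or mutant ZT12 library 3 (0.0264 and 0.0169), and Arl5a also without mutant ZT6 library 0 (0.0382) or mutant ZT18 library 1 (0.0332). At ZT18, the semaphorin receptor gene Plxna2 was at 2.95 ± 0.582 and 1.95 ± 0.0847 FPKM (adjusted p = 0.539).

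The genes with an unadjusted p under 0.05 numbered 1013 at ZT0 (499 higher and 514 lower), 1244 at ZT6 (430 higher and 814 lower), 2085 at ZT12 (1538 higher and 547 lower) and 345 at ZT18 (114 higher and 231 lower). The Thumpd2 call was kept without control ZT6 library 0 or 3, control ZT18 library 2, mutant ZT0 library 2 or 3, mutant ZT6 library 0, 1 or 3, mutant ZT12 library 3 or mutant ZT18 library 0 or 1 (adjusted p from 0.00231 to 0.0483). It was lost without each of the other libraries (adjusted p from 0.0513 to 0.153), with no filter (0.0599), with quantile normalisation (0.0542), with only the groups compared in the fit (0.151) and with lymphocyte and adipocyte scores as covariates (0.0614). Its log2 difference in these 4 settings was -0.59, -0.68, -0.59 and -0.58. The ZT12 count of 3 rose to 446 without mutant ZT12 library 3, to 262 without mutant ZT0 library 2, to 96 without mutant ZT0 library 3, to 6 without mutant ZT18 library 1 and to 5 without mutant ZT6 library 0. Without mutant ZT6 library 1, 1 gene passed at ZT6. At ZT18, 1 gene passed without mutant ZT18 library 0 and 0 genes without library 2 of that group (Nr6a1 adjusted p = 0.0560). With array weights, ZT6 had 232 genes, ZT12 10 and ZT0 1.

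The means of some gene lists lay higher in mutants at some times and lower at others, and the difference between times was not tested for lists. None of the camera calls at single times held with an estimated correlation (adjusted p = 0.933 with an estimated correlation for each) or with fry. The 46 nuclear genes of oxidative phosphorylation were mostly higher in mutants at ZT0 (40 of 46, median 0.12, camera adjusted p = 2.95e-05), lower at ZT6 (45 of 46, median -0.16, adjusted p = 8.08e-07) and lower at ZT18 (39 of 46, median -0.06, adjusted p = 0.00976). At ZT6 the leading members were Cycs, which encodes cytochrome c (-0.65, SE 0.200), and Sdhd, a subunit of succinate dehydrogenase (-0.36, SE 0.106), both with adjusted p = 0.471 (0.0441 and 0.0388 with array weights). Fibroblast and matrix genes were lower at ZT0 (32 of 32, median -0.25, adjusted p = 0.00472), higher at ZT6 (30 of 32, median 0.33, adjusted p = 2.74e-06) and lower at ZT18 (30 of 32, median -0.19, adjusted p = 0.0167). Lymphocyte genes were higher at ZT6 (22 of 22, median 1.12, adjusted p = 1.11e-10) and ZT18 (22 of 22, median 0.98, adjusted p = 3.12e-11), while at ZT0 21 of 22 were lower (median -0.36, adjusted p = 0.112). Slow fibre genes were lower at ZT12 (15 of 19, median -0.30, adjusted p = 2.66e-05), with Tnnt1 at -1.19 (SE 0.332, adjusted p = 0.121, and 0.0278 without mutant ZT0 library 2). Core clock genes were lower at ZT6 (19 of 23, median -0.15, adjusted p = 0.0167). Adjusted over the list alone, 1 slow fibre gene passed at ZT12, and 0 genes of the other lists passed at the times given above for each. Oxidative phosphorylation genes had no camera call at ZT12 (27 of 46 higher, median 0.05), where 1 of them passed adjusted over the list alone. At ZT6, 9 of them had an unadjusted p under 0.05.

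The genotype difference changed with time for no gene after adjustment. The limma F test gave 0 of 11975 genes (smallest adjusted p = 0.196) and 1684 genes at an unadjusted p under 0.05. Rab6a, the deubiquitinase gene Usp14 and the ubiquitin ligase gene Rnf7 were among the genes with the smallest p (adjusted p = 0.196 for each). The log2 difference was 0.50 at ZT12 and -0.32 at ZT6 for Rab6a, 0.37 and -0.25 for Usp14, and 0.44 and -0.43 for Rnf7. Rab6a, Usp14 and Rnf7 passed without mutant ZT0 library 2 (adjusted p = 0.0371 for each), without mutant ZT0 library 3 (0.0212, 0.0281 and 0.0281) and with array weights (0.0284, 0.0463 and 0.0284). Usp14 and Rnf7 also passed without mutant ZT12 library 3 (0.0456 and 0.0396). The count rose to 93 without mutant ZT0 library 3, to 25 without mutant ZT12 library 3, to 21 without mutant ZT0 library 2 and to 42 with array weights.

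In control muscle 665 genes had a 24 h rhythm, and among them clock genes, glucocorticoid-responsive genes and endothelial genes were enriched, and less steadily atrophy genes. The activator Arntl was highest at ZT6 (15.2 ± 1.52 FPKM) and low at ZT12 (4.65 ± 1.2) and ZT18 (3.75 ± 3.55; SD, n = 4 each). Its targets ran in other phases, with Nr1d1 at 60.4 ± 13.7 FPKM at ZT12 and 17.5 ± 5.17 at ZT0, and Per2 at 8.29 ± 2.75 at ZT18 and 0.840 ± 0.395 at ZT6. Dbp, a transcription factor driven by the clock, was at 62.8 ± 33.3 FPKM at ZT18 and 9.13 ± 2.11 at ZT6. Of 23 core clock genes tested, 14 were rhythmic (limma, adjusted over all genes) and 20 adjusted over the list alone (Fisher's exact test for the list, adjusted p = 3.33e-11).

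Amplitudes on the log2 scale in controls were 1.58 for Angptl7, a secreted angiopoietin-like protein (adjusted p = 0.00361, peak at ZT 20), 1.55 for Dbp (adjusted p = 1.29e-06, peak at 15.6), 1.53 for Arrdc2, an arrestin-domain gene (adjusted p = 0.000249, peak at 16.4), and 1.41 for Ddit4, an inhibitor of mTORC1 (adjusted p = 0.0136, peak at 16.5). G0s2, an inhibitor of lipolysis, had an amplitude of 1.03 (adjusted p = 0.000396, peak at 1.44), and Tbc1d1, a regulator of glucose transport, 0.83 (adjusted p = 4.16e-05, peak at 23.7). Glucocorticoid-responsive genes were enriched among rhythmic genes (9 of 26, 16 adjusted over the list alone, adjusted p = 8.86e-05), among them Per1, Arrdc2, Klf9 and Fbxo32. Endothelial genes were also enriched (6 of 20, 9 adjusted over the list alone, adjusted p = 0.00530), with Kdr, Aqp1, Cldn5 and Pecam1 passing. So were atrophy genes (5 of 20, 8 adjusted over the list alone, adjusted p = 0.0281), with Asb2 and Fbxo32 passing, but this was lost in 13 of 32 fits with 1 library left out (adjusted p from 0.0561 to 0.668), without control ZT18 library 0 and mutant ZT0 library 2 together (0.0663) and with the F test of any difference between times (0.136). The other 3 enrichments were kept in all of them. The glucocorticoid list shares 6 genes with the atrophy list and 1 with the clock list. Insulin signalling was not enriched (6 of 40, 7 adjusted over the list alone, adjusted p = 0.123), nor were genes of glucose use (4 of 42, 4 adjusted over the list alone, adjusted p = 0.665), in which Hk2, the hexokinase gene of muscle, peaked at 18.2 (amplitude 0.34, adjusted p = 0.00342). The count of rhythmic genes was 1221 in a fit of control libraries alone, 2233 with array weights and 390 with a minimum mean of 5 FPKM.

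**Figure D3:**
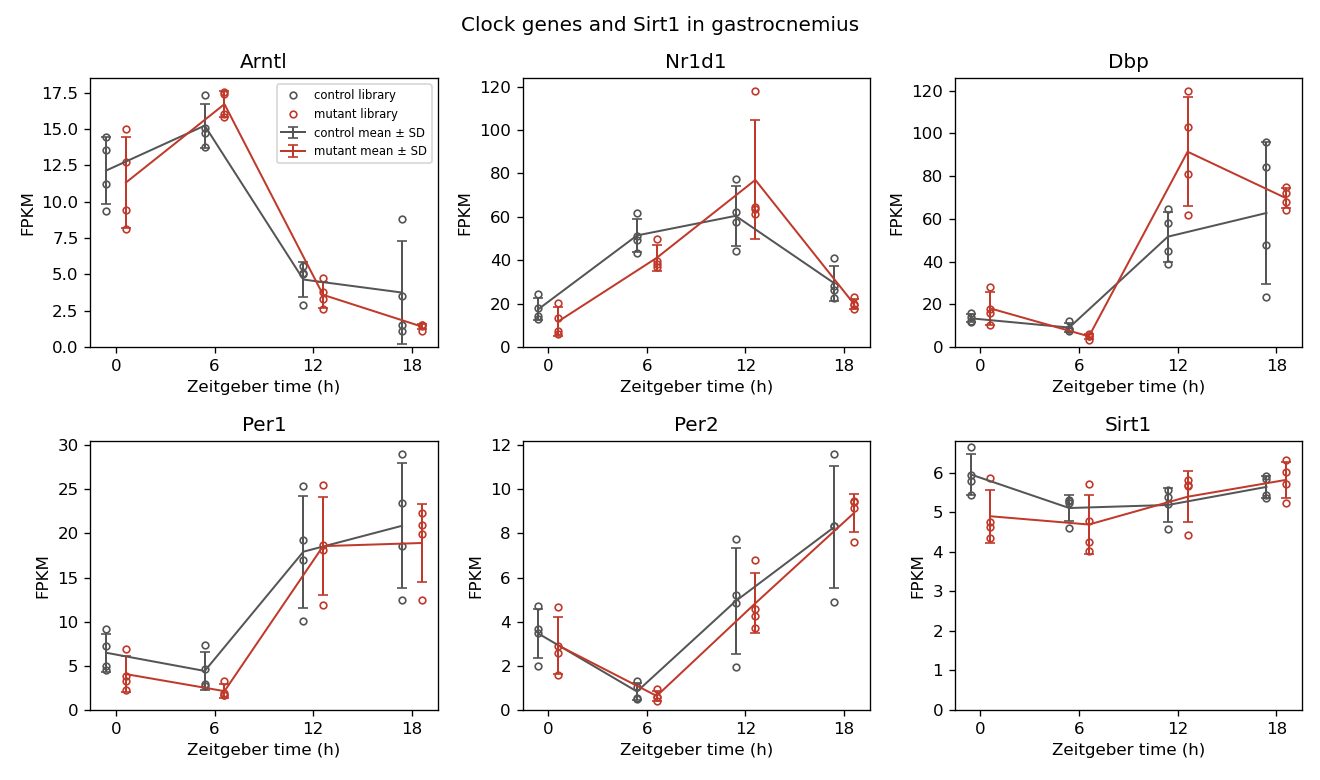
FPKM of Arntl, Nr1d1, Dbp, Per1, Per2 and Sirt1 (vertical axes, from 0) against Zeitgeber time in hours (horizontal axes), with 1 open circle per library in controls (grey) and mutants (red), slightly offset; lines join group means and bars show the SD of 4 mice. In both genotypes Arntl is highest at ZT6 and Per2 at ZT18, and Sirt1 stays between 4.02 and 6.65 FPKM.

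In mutant muscle 470 genes were rhythmic, and the clock genes ran in the same phases as in controls. Arntl was at 16.7 ± 0.902 FPKM at ZT6 and 1.41 ± 0.185 at ZT18, Nr1d1 at 77.0 ± 27.4 at ZT12 and 11.8 ± 6.5 at ZT0, and Dbp at 91.4 ± 25.5 at ZT12 and 5.02 ± 1.14 at ZT6 (SD, n = 4 each). Of the core clock genes, 15 of 23 were rhythmic (17 adjusted over the list alone, adjusted p = 6.68e-15). The largest amplitudes were 2.13 for Dbp (adjusted p = 3.46e-09), 1.86 for Arrdc2 (adjusted p = 9.42e-06) and 1.66 for Per1 (adjusted p = 1.69e-07). Glucocorticoid-responsive genes were enriched (11 of 26, 13 adjusted over the list alone, adjusted p = 1.92e-08). Genes of lipid synthesis and storage (5 of 29, 6 adjusted over the list alone) were also enriched, with G0s2 and Scd2 passing, and so were atrophy genes (4 of 20, 6 adjusted over the list alone) and immediate early genes (4 of 21, 9 adjusted over the list alone), each with adjusted p = 0.0461. With 1 of 32 libraries left out, the call of the lipid list was lost in 23 fits (adjusted p from 0.0518 to 0.312), that of the atrophy list in 7 (0.0518 to 0.185) and that of the immediate early list in 24 (0.0501 to 0.429), and all 3 were lost with the F test of any difference between times. The atrophy call was also lost without control ZT18 library 0 and mutant ZT0 library 2 together (0.0897), and the immediate early call with a pseudocount of 0.1 (0.191). The clock and glucocorticoid enrichments were kept in all of them. Endothelial genes were not (3 of 20, 6 adjusted over the list alone, adjusted p = 0.167).

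Rhythms found in both genotypes were alike in timing. The overlap was 274 genes, against 26.1 for independent lists, and in 270 of them (98.5%) the peaks lay within 3 h. The median peak difference was 0.0710 h and the median log2 amplitude ratio 0.03. In controls 331 of 665 rhythmic genes peaked between ZT21 and ZT3, and 149, 54 and 131 in the following windows of 6 h. In mutants 115 of 470 peaked between ZT21 and ZT3, and 175, 37 and 143 in the following windows. Of the 391 genes that passed only in controls, 176 had an unadjusted p under 0.05 in mutants. The mutant count was 249 in a fit of mutant libraries alone, 752 with array weights and 287 with a minimum mean of 5 FPKM.

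**Figure D4:**
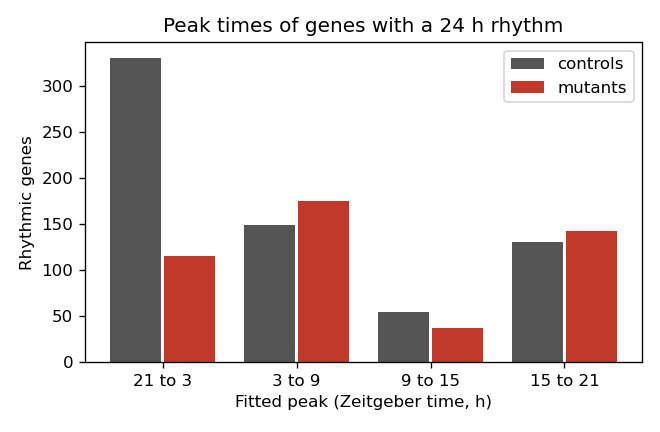
Number of genes with a 24 h rhythm (vertical axis, from 0) by the window of Zeitgeber time, in hours, that holds the fitted peak (horizontal axis), in controls (grey) and mutants (red). The window from ZT21 to ZT3 holds 331 control and 115 mutant genes, and counts in the other windows are closer; the counts carry no error bars.

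No gene differed in its 24 h rhythm between genotypes after adjustment. The limma F test of the difference gave 0 of 11975 genes (smallest adjusted p = 0.468) and 640 genes at an unadjusted p under 0.05. Adjusted over the 861 genes rhythmic in either genotype, a set chosen from the same data, the smallest adjusted p was 0.0336. Among genes with large amplitudes, Cyp26b1, which degrades retinoic acid, had an amplitude of 1.24 in controls and 0.32 in mutants (limma adjusted p of the difference 0.880). For Coq10b, a gene of coenzyme Q function, the amplitude was 0.67 and 1.09 (adjusted p = 0.880). Sgk1 had amplitudes of 0.40 and 0.81 (adjusted p of the difference 0.880), and Srebf1, a regulator of lipid synthesis, 0.47 and 0.21 (adjusted p = 0.880). No core clock gene passed adjusted over the list alone, and 4 of 23 had an unadjusted p under 0.05.

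The core clock was not detectably weaker or shifted in mutants. Of 19 clock genes rhythmic over both genotypes, 14 had a larger amplitude in mutants, with a median log2 ratio of 0.31 or 1.24-fold (permutation of genotype within time, p = 0.0636). The amplitude of Arntl was 1.19 in controls and 1.60 in mutants, that of Nr1d1 0.96 and 1.44, and that of Per1 1.21 and 1.66, while Cry1 had 0.48 and 0.41 and Ciart 1.44 and 1.43. With median-ratio scaling the median ratio was 0.40 (permutation p = 0.00979). Leaving out 1 library gave ratios from 0.198 (without mutant ZT6 library 0, permutation p = 0.267) to 0.469 (without control ZT18 library 2, permutation p = 0.00415), and p stayed over 0.05 in 12 of 32 such fits. These left out control ZT0 library 2, ZT6 library 2, ZT12 library 1 or ZT18 library 0 or 1, or mutant ZT0 library 0, 1 or 3, ZT6 library 0, ZT12 library 2 or ZT18 library 2 or 3. Without control ZT18 library 0, whose clock genes lay apart from their group, the ratio was 0.208 (permutation p = 0.0929), and without mutant ZT0 library 2 as well, a choice made after seeing the data, 0.222 (permutation p = 0.0907). Without each of the other libraries the permutation p was between 0.00415 and 0.0482. Peak times differed by a mean of -0.528 h (mutant minus control, permutation p = 0.379), with 7 of 19 genes later in mutants; without control ZT12 library 3 the mean was 0.0993 h (permutation p = 0.824).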

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

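All tests of explanations given here were chosen after the result was seen.

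The genes higher in mutants over all times, Nr6a1, Gm13490 and Arl5a, lie on chromosome 2. Nr5a1, the gene whose promoter drives Sf1-Cre, lies there on the minus strand, and the side where its transcription starts is 8827 bp from Nr6a1. All 3 genes higher in mutants passed with lymphocyte and adipocyte scores as covariates (0.74, 1.39 and 0.36), which argues against lymph node or fat tissue as the whole cause. Linkage along the whole of chromosome 2 stays open: 15 of 100 regroupings had as many other genes there with an unadjusted p under 0.005 (10 in the real grouping, 56 in the highest other), while chromosome 2 held 16.4% of genes under that p against 7.78% of those tested (odds ratio 2.34, 1-sided Fisher's exact p = 0.0185, which takes genes as independent; 12 of 100 regroupings had as large a share). A test of the region alone was added after that result. Of 23 other genes between Nr6a1 and Arl5a, Lypd6, Rnd3 and Nmi reached that p. In 3 of 100 regroupings, the real one included, as many did (highest other 3). Lypd6 was lower in mutants (-0.35), while Rnd3 (0.24) and Nmi (0.23) were higher. The called genes themselves set the bounds of this region, so the test is not independent of the result. Alleles or gene copies that travel with the Cre transgene remain a candidate for these differences and were not told apart. In mutant ZT18 library 1, 3 of 5 genes from Lypd6 to Arl5a lay under 0.5 of the mutant difference: Lypd6 (-0.84), Gm13490 (0.18) and Arl5a (-0.13). Mutant ZT6 library 2 also had 3, Lypd6 (0.39), Rnd3 (0.28) and Arl5a (0.25), but its Gm13490 was at 1.09. Rnd3 and Nmi, which lie between Lypd6 and Arl5a, were at 1.40 and 1.43 in mutant ZT18 library 1. Over mutant libraries they ranged from -0.14 to 2.31 and from -0.54 to 2.40, so their values in 1 library cannot decide whether a segment was missing. Whether this mouse lacked linked alleles stays open. An effect of the SIRT1 deletion itself cannot be separated from the transgene because no control carried Cre.

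Lymphocyte and adipocyte genes were high in some libraries of both genotypes. The lymphocyte score followed the score of 5 lymph node stroma genes within groups (Pearson r = 0.977, Spearman rho = 0.975, both permutation p = 1e-05, the smallest 100000 draws can give, and adjusted p = 8e-05 over 8 lists; r = 0.977 without the 2 farthest libraries), so lymph node taken with the muscle is a candidate source; the stroma list had been shortened after a first run. Of the 5 stroma genes, Madcam1 reached at most 0.436 FPKM and Chst4 at most 0.328 FPKM, and they were listed at 0 in 14 and 16 libraries. The stroma score thus rests mainly on Cxcl13, Ccl19 and Glycam1. Blood is argued against by the erythroid score (r = -0.0211), and a lower share of fibres with every other cell type raised alike by the lowest r of fibroblast, endothelial and Schwann cell scores (-0.0754). Genotype stays open, since the lymphocyte score difference had a permutation p of 0.104.

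The clock genes of control ZT18 library 0 lay apart from their group. By root mean square distance over 23 clock genes this library was nearest to ZT 12 (0.509) but almost as near to ZT0 (0.525), and farther from ZT6 (0.693) and its own time (0.712), so that it resembled no time clearly; 30 of 32 libraries were nearest to their own time. The other exception, control ZT12 library 1, was nearest to ZT18 (0.277, against 0.455 to its own time), so 1 control library could be the partner of a swap. With each left out of the other's reference the distances were 0.499 against 0.712 and 0.283 against 0.455. A swap, another wrong label and a mouse with a shifted clock cannot be told apart, because the distances to ZT12 and ZT0 differ by less than the margin of 0.1 that was set after the result, and no biological explanation was tested.

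Among 96 groups of 4 libraries examined, 7 held a library far from the others, where chance gives 4.8. Sirt1 was at 4.60 FPKM in control ZT6 library 1, against 5.22 to 5.32 in the others. In mutant ZT12 library 0 Sirt1 was at 4.42 FPKM, against 5.65 to 5.80. Arntl was at 1.13 FPKM in mutant ZT18 library 3, against 1.48 to 1.52. Per2 was at 7.63 FPKM in mutant ZT18 library 0, against 9.17 to 9.48. Nr1d1 was at 118 FPKM in mutant ZT12 library 1, against 61.5 to 64.6. The lymphocyte score was 0.33 in control ZT6 library 3, against -0.88 to -0.75, and 1.21 in mutant ZT0 library 1, against -0.89 to -0.73.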

How the results depend on the processing

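The alternatives with covariates, without genes listed at 0, and without control ZT18 library 0 and mutant ZT0 library 2 together, and leaving out each library for the number of enriched lists, and every alternative for single enriched lists and for Gm13490 at each time, were chosen after seeing the data; where a count moved, the cause was not tested except as stated. With a minimum mean of 5 FPKM, which removes Nr6a1 and Gm13490 from the genes tested, 1 gene differed over all times, 0 at ZT0, 0 at ZT6, 0 at ZT12 and 0 at ZT18, and 390 genes were rhythmic in controls and 287 in mutants. Array weights gave 1 gene at ZT0, 232 at ZT6, 10 at ZT12, 42 with a genotype effect that depends on time, and 2233 and 752 rhythmic genes. Quantile normalisation gave 0 genes at ZT6 and 0 at ZT18. With only the groups compared in the fit, and so fewer samples, there were 0 genes at ZT12, 1 at ZT18, and 1221 and 249 rhythmic genes. Without the 2 libraries together there were 236 genes at ZT12, 4 at ZT18, 27 with an effect that depends on time and 1212 rhythmic in controls. Of 140 list tests, 0 passed with an estimated correlation, 0 with fry and 22 with covariates. The core clock amplitude ratio was 0.40 with median-ratio scaling.

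Leaving out each library in turn gave 3 to 4 genes over all times, 2 to 3 at ZT0, 1 to 2 at ZT6, 2 to 446 at ZT12, 0 to 3 at ZT18, 0 to 93 with an effect that depends on time, 471 to 948 rhythmic in controls, 340 to 571 in mutants, 0 to 0 with a rhythm difference, 33 to 47 list calls, 3 to 5 lists enriched in controls, amplitude ratios of 0.198 to 0.469, phase shifts of -0.768 to 0.0993 h and Sirt1 differences of -0.0880 to -0.0482. The phase shift turned to 0.0993 h only without control ZT12 library 3. Of 98 rhythm results of named genes that passed, 75 passed under every setting run, and of 21 that did not pass, 11 passed under none. Depth limits genes with low FPKM, for which log2(FPKM + 1) understates changes.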

Other observations

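The hypotheses of this part, on other groupings of the libraries, were tested after the results were seen.

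Genes known from brown fat and from lymph node varied widely between muscle libraries. Ucp1, the uncoupling protein of brown fat, ranged from 0.418 to 165 FPKM (median 12.1, highest in mutant ZT12 library 3), and Cidea, a lipid droplet protein, from 0.504 to 114 FPKM (highest in mutant ZT18 library 3). Cxcl13, a chemokine of lymphoid stroma, ranged from 0.235 to 24.8 FPKM, and Glycam1, a mucin of lymph node vessels, reached 11.1 FPKM in mutant ZT6 library 1 and was listed at 0 in 11 libraries. The B cell receptor gene Cd79b reached 20.1 FPKM in control ZT12 library 3. Within groups the lymphocyte score correlated with the brown fat score (Pearson r = 0.645, Spearman rho = 0.651, adjusted permutation p = 0.000267 and 0.000400 over 8 lists), and r was 0.547 without the 2 farthest libraries.

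Other groupings of the same libraries show which counts chance can give. Over all times, 3 of 100 groupings gave at least the 3 genes of the real one, but the highest other gave 355, which points to a structure of the samples that was not traced here. At ZT6, ZT12 and ZT18, 1 of 35 groupings, the real one included, gave as many genes as the real ones (2, 3 and 2, highest other 1 each). This share (0.0286) is the smallest that 35 groupings can give, and it was not adjusted for the number of times tested. The real counts thus lay above those of every other grouping, but this test alone cannot exclude chance for them. With only the groups compared in the fit, the counts were 3 at ZT6, 0 at ZT12 and 1 at ZT18. With quantile normalisation the counts at ZT6 and ZT18 were 0. Chance cannot be excluded for the genes with an unadjusted p under 0.05 at ZT0 (real 1013, as many in 19 of 35, highest other 2054). The same holds at ZT12 (real 2085, as many in 2 of 35, highest other 2672) and ZT18 (real 345, 19 of 35, highest other 1020). At ZT6, 1 of 35 gave as many as the real 1244 (highest other 1163). At ZT0 the count alone does not exclude chance, with 5 of 35 (real 2, highest other 12). The genes called there, Nr6a1 and Gm13490, had no overlap between control and mutant libraries at any time (Nr6a1 limma adjusted p = 4.63e-05 at ZT0). They were picked from these same libraries, so the lack of overlap at ZT0 is not separate support. With only the groups compared in the limma fit, the adjusted p of Nr6a1 at ZT0 was 0.558. Both genes were also higher in mutants at the other times, in other mice. For an effect that depends on time, 100 of 100 groupings gave at least the real 0 (highest other 3); at an unadjusted p under 0.05, 3 of 100 gave at least the real 1684 (highest other 1951). Chance can be excluded for rhythms in controls, with 1 of 100 (real 665, highest other 6). In mutants the count alone does not exclude it, with 7 of 100 (real 470), and the highest other, 1702, again points to a structure that was not traced. Part of these rhythms recurred in the separate control mice, in 274 genes against 26.1 for independent lists, with peaks within 3 h in 98.5%. Core clock genes were enriched as well (15 of 23, Fisher's exact test, adjusted p = 6.68e-15). Both comparisons take genes as independent, and a harvest day or pool shared by both genotypes would enter them. The rhythm tests of both genotypes also share 1 estimate of the spread per gene. A gene with a low spread can therefore pass in both, and 26.1 is not an exact expectation. Both comparisons describe the likeness of the genotypes and do not measure how far chance is excluded. For the rhythm difference 100 of 100 gave at least the real 0 (highest other 25).

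For gene lists, 41 of 100 groupings gave at least the real 40 calls (highest other 57), so the camera calls as a whole are not beyond chance. The difference of 195 in the number of rhythmic genes between genotypes was reached in 46 of 100 groupings (highest other 680), and the difference of 216 in genes that peak between ZT21 and ZT3 in 19 of 100 (highest other 415). Chance can be excluded for neither.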
